A study of Mus musculus with 15 samples.

How the data were processed

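RNA of mouse induced renal tubular epithelial cells (iRECs) was sequenced from 5 culture conditions with 3 libraries each, 15 in all: 2D culture, Matrigel, fibrin, collagen I, and cells dispensed by an inkjet bioprinter in fibrin and collagen I. The replicates of each condition came from passages 35, 48 and 53 of 1 cell line, were prepared in parallel from a common pool of cells and were harvested on day 7. They are therefore cultures of 1 line and not independent animals. The values used here were the authors' 4 tables of results, 1 per microenvironment against 2D, each for 27179 genes and 6 libraries. They hold 1 value per gene and comparison, with 0 columns of values per sample, so the depth of each library is unknown and no interval for counting error can be given. The name of the table for the printed cultures mentions collagen, while the labels of those libraries give fibrin and collagen I.

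Per the submitters' processing notes, the tools were FastQC 0.72, Trim Galore 0.4.3, STAR 2.6.0b-1, featureCounts 1.6.3 and DESeq2 1.22.1 on genome build mm10. The strand setting, the gene annotation and whether passage was a term of the fit are not given in the sources used here. The base mean in the deposited tables is a signal, the mean over the fitted libraries of read counts that the authors divided by size factors. The fold change in the deposited tables is a log2 value of the microenvironment over 2D, and the authors gave its standard error on the same log2 scale. The Wald statistic in the deposited tables is a score, the log2 fold change over its standard error. Each p-value in the deposited tables is the authors' two-sided p-value of that score, and the adjusted p-value is missing for genes of low base mean. Benjamini-Hochberg adjustment of the deposited p-values returned the deposited adjusted values within 6.31e-15. The direction of the fold changes was checked through the level in 2D that each table implies, which varied between the tables by a median SD of 0.0113 on the log2 scale, against 0.0947 or more with any sign turned. Fold changes were shrunken towards 0 by the authors' fit: ratios of implied levels exceeded the deposited fold changes on the log2 scale by a median factor of 1.11 for Matrigel, 1.10 for fibrin, 1.09 for collagen I and 1.22 for the printed cultures. Genes whose implied value was above 1 and exceeded the deposited one by more than 1 were counted after seeing the data, with the level in 2D taken as the median of the other 3 tables. Strong shrinkage of this kind goes with few reads or a wide spread between replicates. Of the 27179 gene identifiers, 93.0% were in the RefSeq annotation of GRCm38, which gave coordinates counted from 1, and 874 had no symbol.

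A p-value was given for 19384 genes in the Matrigel table, 19431 for fibrin, 19669 for collagen I and 19578 for the printed cultures, and an adjusted p for 14602, 14636, 14064 and 15116. The 10 genes with the highest base means took 4.09%, 4.13%, 4.29% and 4.44% of the summed base means. Among genes with a base mean of 100 or more, the median standard error of a log2 fold change was 0.19 for Matrigel, 0.23 for fibrin, 0.23 for collagen I and 0.22 for the printed cultures, which sets the precision of single values. A gene was called changed where the authors' adjusted p was under 0.05. No test was refitted, since that needs values per library.

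Before the data were examined, 33 gene lists, the tests, the rule for named genes and most alternatives were fixed. Lists with at least 5 members were tested with cameraPR of limma 3.58.1 on the Wald statistics, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 32 lists and 4 comparisons, 128 tests. The list of reprogramming factors was too short to test. A correlation estimated from the samples could not be had, so a preset correlation of 0.05 stood beside it: 40 of the 50 calls passed with that value too. Of the 32 lists, 4 were called in all comparisons and 8 in none. The latter were loop of Henle, distal tubule and collecting duct, fibrinolysis and coagulation, YAP/TAZ targets, WNT pathway, nephron development, podocyte markers and endothelial markers, with a smallest adjusted p of 0.056 for YAP/TAZ targets. In Matrigel only 5 of 15 loop of Henle and 14 of 26 distal tubule and collecting duct genes with a p-value had an adjusted p. In collagen I 4 of 11 endothelial markers had one. Genes of low base mean add little to a list test, so a change in these lists is not excluded. YAP/TAZ targets were better covered, with 20 of 21 in Matrigel. Markers of podocytes, endothelial cells, immune cells and smooth muscle were tested as lists of other cell types.

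Differences between 2 microenvironments were the difference of their log2 fold changes over the root of the summed squared standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment within each of 6 pairs. Lists were tested on this statistic in the same way, over 192 tests. Overlaps were set beside those of independent lists and of 20 simulations in which unchanged groups shared their controls and the lists had the observed sizes.

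The named genes were, in each comparison, the 5 with the highest and the 5 with the lowest log2 fold change among those with an adjusted p under 0.05, a base mean of 100 or more and a symbol that is no predicted gene. Reprogramming factors were named too, and up to 4 members of each described list with the smallest adjusted p, as well as well-known markers that did not pass. Some genes that this rule covers are not reported here. For differences they were the 4 largest in each direction by the same rule, and for genes changed in all comparisons the 6 highest and 6 lowest by their smallest absolute log2 fold change. A further 4 lists, targets of NRF2, acute phase, squamous differentiation and targets of LXR, were written after fold changes had been seen. Their members whose values had not been looked at were tested apart.

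The alternatives were an adjusted p under 0.01, a minimum absolute log2 fold change of 1, adjustment over every gene with a p, minimum base means of 10 and 100, and an empirical null. The empirical null took the centre and scale of the Wald statistics from their middle 50%, and its scales were 1.27 for Matrigel, 1.35 for fibrin, 1.57 for collagen I and 1.11 for the printed cultures. Lists were also tested on log2 fold changes, on ranks, with base means of 100 or more and on residuals after GC content and transcript length in 20 bins. Differences were repeated with a correlation of 0.5 between the 2 estimates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and R 4.3.3 were used.

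The tests were checked on simulated data with 200 changed genes among 14042. The changed genes were drawn only from those with a base mean of 100 or more in collagen I. Errors were normal and no shrinkage was applied, so the shares found need not hold for genes with fewer reads or shrunken fold changes. At a log2 size of 1, 72.5% were found in a comparison with the standard errors of collagen I against 2D, with 3 false calls, and 14.0% in a difference between collagen I and fibrin, with 0 false calls. At a log2 size of 2, 100% and 99.5% were found, with 8 and 1 false calls. Of 200 random lists of 30 genes, 4% had a p under 0.05, and 10 of 10 shifted lists were found. The statistics for these lists were drawn independently for each gene, so correlation between list members was not checked. Reads of genes with close copies (the Ugt1a, Serpina3, Sprr2, Gsta and Oas1 families) are hard to assign, and their values are uncertain. Raw reads were not used here.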

Results

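Induced renal tubular epithelial cells (iRECs) are mouse fibroblasts that were turned into tubule-like epithelial cells by forced expression of transcription factors, among them Emx2, Hnf4a and Pax8. Their RNA was sequenced in 5 culture conditions with 3 libraries each, 15 libraries in all. The control cells grew on flat plates (2D). The other 4 conditions were 3D cultures in Matrigel, a basement membrane extract, in fibrin, the polymer of blood clots, in collagen I, the main fibrillar collagen, and cells dispensed by an inkjet bioprinter in fibrin and collagen I, called printed cultures here. The 3 replicates were started at passages 35, 48 and 53 of 1 cell line, and RNA was taken on day 7. The values are those of the authors' 4 comparison tables, 1 for each microenvironment against the same 3 libraries in 2D. Each table gives 1 mean level and 1 fold change per gene, so the depth of each library and the direction in each replicate are unknown here. The mean levels, in units of 1e6 normalized reads, summed to 43.8 in the Matrigel table, 43.1 for fibrin, 42.8 for collagen I and 45.4 for the printed cultures. Fold changes are log2 values of the microenvironment over 2D, and each number after ± is the authors' standard error. A gene is said to have risen, fallen or changed where the authors' adjusted p lay under 0.05. Risen and fallen members of a list are counted out of its members with a p-value. Members without an adjusted p could pass only when adjusted over the list alone. The highest and lowest genes of a comparison or difference are given among those with a base mean, the mean of the normalized read counts, of 100 or more.

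Introduced factors were checked first. The authors' deposited table for Matrigel gave base means of 20398 for Emx2, 10945 for Hnf4a and 20755 for Pax8. Pax8 (gene 18510, chromosome 2, 24420551 to 24475599, GRCm38) fell in fibrin, log2 -0.63 ± 0.19 with adjusted p = 0.015, and in collagen I, log2 -0.66 ± 0.20 with adjusted p = 0.016, in the authors' deposited tables. Neither Pax8 call passed when the spread of the Wald statistics was taken from their own middle part. Emx2 and Hnf4a did not pass in any of the 4 comparisons. Transcripts of the introduced and of the cells' own copies were not separated.

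**Figure D1:**
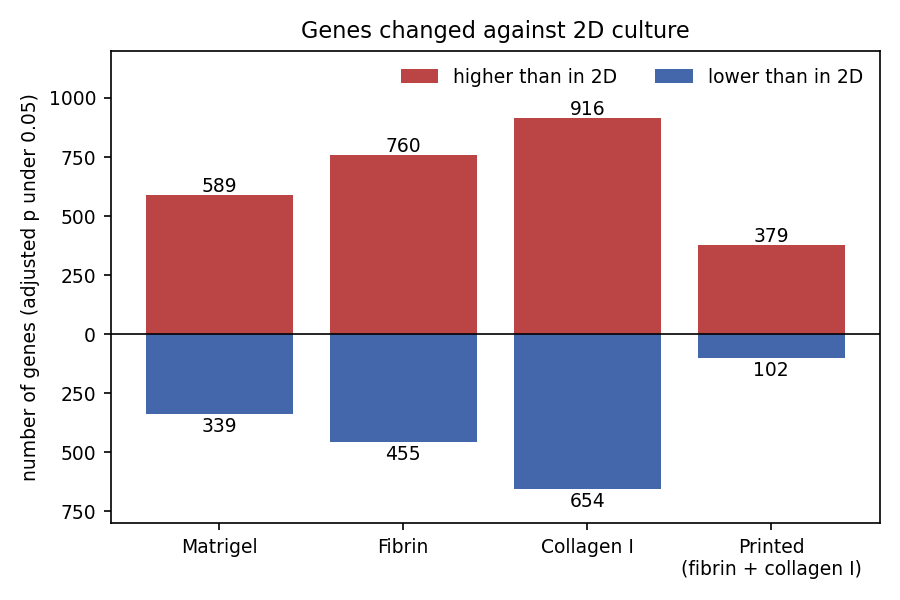
Number of genes with an adjusted p under 0.05 against 2D culture in each of the 4 microenvironments, higher genes above 0 and lower genes below 0. Collagen I had 916 higher and 654 lower genes, and the printed cultures 379 and 102.

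The comparison of Matrigel with 2D asked what a basement membrane gel changed in these cells. Replication and mitosis genes, sterol synthesis genes and several proximal tubule genes were higher in Matrigel, and actin, mesenchymal and matrix protease genes were lower. The highest genes with a base mean of 100 or more in the authors' deposited table were Kap, an androgen-regulated protein of the proximal tubule, at log2 3.02 ± 0.26, and Anxa13, an epithelial annexin, at 2.92 ± 0.28. They were followed there by Cyp24a1, the enzyme that inactivates vitamin D, at 2.84 ± 0.28, the glucuronosyltransferase Ugt1a7c at 2.82 ± 0.26 and Papss2, which makes the donor for sulfation, at 2.65 ± 0.29. Nox4, an NADPH oxidase of the kidney, fell most of these in that deposited table of the authors, log2 -2.93 ± 0.28. Prrt4 (-2.90 ± 0.24), the actin-associated Pdlim1 (-2.29 ± 0.26), Mamdc2 (-2.07 ± 0.26) and Plxdc1 (-1.97 ± 0.29) came next in the authors' deposited table. Kap lies on chromosome 6 from 133849855 to 133853667 and Nox4 on chromosome 7 from 87244430 to 87398710 of GRCm38.

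Among 32 genes of DNA replication and S phase, 20 rose in Matrigel and none fell, with 27 risen when adjusted over the list alone (list test adjusted p = 6.9e-26). Rrm2, a ribonucleotide reductase subunit, was at log2 1.46 ± 0.18 and thymidine kinase Tk1 at 1.11 ± 0.23 in the authors' deposited table. Of 30 genes of G2/M and mitosis, 8 rose (15 adjusted over the list alone), among them Ube2c at 1.03 ± 0.21 and Aurkb at 1.02 ± 0.21 in the authors' deposited table. The mitotic list passed with adjusted p = 1.7e-13. Of 25 genes of cholesterol biosynthesis, 8 rose and 14 did when adjusted over the list alone (adjusted p = 8.7e-15). The isomerase Idi1 led them at log2 1.31 ± 0.19 in the authors' deposited table. Amino acid and unfolded protein stress genes were also higher, with 10 of 30 risen, 15 adjusted over the list alone, and adjusted p = 1.6e-10. The authors' deposited table had Herpud1, a protein of the degradation machinery of the endoplasmic reticulum, at log2 0.96 ± 0.16 and cystathionine gamma-lyase Cth at 1.01 ± 0.23. Hypoxia and glycolysis genes fell in 3 of 35 cases (3 adjusted over the list alone), and the list was lower with adjusted p = 1.6e-05. Adm, the vasoactive peptide adrenomedullin, fell to log2 -1.49 ± 0.29 in the authors' deposited table.

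Of 36 proximal tubule genes with a p-value, 26 of them with an adjusted p, 8 rose and 2 fell in Matrigel. When adjusted over the list alone, 9 rose and 2 fell. Besides Kap, the authors' deposited table had Acsm2 at log2 1.38 ± 0.22 and the cadherin Cdh6 at -1.15 ± 0.25. The list was higher with adjusted p = 0.00053, and its adjusted p was 0.11 when ranks were tested. Epithelial junction and polarity genes did not shift as a list, with 6 risen and 2 fallen of 52 (6 and 2 adjusted over the list alone). E-cadherin (Cdh1) rose by log2 0.90 ± 0.16 and Epcam by 0.87 ± 0.16, while the tight junction claudin Cldn1 fell to -1.89 ± 0.24 in the authors' deposited table. Mesenchymal and fibroblast genes were lower, with 8 of 33 fallen and 1 risen, 12 and 1 adjusted over the list alone (adjusted p = 9.8e-06). Fibronectin (Fn1) fell to log2 -1.97 ± 0.21, the transcription factor Zeb2 to -1.36 ± 0.27 and Fbln2 to -1.64 ± 0.31, whereas Twist2 rose to 0.92 ± 0.17 in the authors' deposited table.

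Actin and SRF/MRTF target genes, which follow the state of the actin cytoskeleton, fell in 6 of 29 cases in Matrigel and rose in 1, with the same numbers adjusted over the list alone. The test of this list gave adjusted p = 4.8e-06. Caldesmon (Cald1) was at log2 -1.50 ± 0.16, Fhl1 at -1.09 ± 0.18 and smooth muscle actin Acta2 at -1.35 ± 0.30 in the authors' deposited table. Matrix proteases and their inhibitors fell in 9 of 33 cases and rose in 2, 11 and 2 adjusted over the list alone (adjusted p = 2.9e-05). The authors' deposited table had Mmp25 at -1.18 ± 0.24 and Adamts1 at -1.03 ± 0.21. TGF-beta target genes were lower with adjusted p = 0.00029, with 3 of 22 fallen and 2 risen, 8 and 2 adjusted over the list alone. The risen members were the inhibitors of differentiation Id1 (1.69 ± 0.22) and Id2 (1.09 ± 0.21) in the authors' deposited table, and Id2 was singled out after its value was seen. Interferon response genes had 1 of 34 fallen and none when adjusted over the list alone. Their adjusted p was 0.035 and rose to 0.20 with a preset correlation of 0.05.

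In all, 928 of 14602 genes with an adjusted p changed in the authors' deposited table for Matrigel, 589 higher and 339 lower, and 323 of them had an absolute log2 fold change of 1 or more. With the spread of the Wald statistics taken from their own middle part (an empirical null), 373 genes passed. The 10 genes with the highest and lowest values passed there too, as did 57 of the 83 named genes that had changed, 7 of the 20 replication genes, 2 of the 8 mitotic genes and 2 of the 8 cholesterol genes.

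The comparison of fibrin with 2D asked the same question for a clot-like gel. Cytokine genes and tubular injury genes were higher in fibrin, together with replication, mitosis and sterol synthesis genes. Hypoxia genes were lower. Ugt1a9, a drug-conjugating glucuronosyltransferase, had the highest value among genes with a base mean of 100 or more in the authors' deposited table, log2 5.68 ± 0.32 or 51.2-fold, at a base mean of 361. It lies on chromosome 1 from 88070779 to 88220002 (GRCm38) and shares its end with Ugt1a7c, so reads of this gene family are hard to assign and its values are uncertain. Lbp, which binds bacterial lipopolysaccharide in serum, stood at log2 4.52 ± 0.28, Anxa13 at 4.45 ± 0.26, Gimd1 at 4.29 ± 0.32 and Cp, the plasma copper protein ceruloplasmin, at 4.05 ± 0.31 in the authors' deposited table. The lowest there above the same base mean were the secreted peptide gene Ostn at -3.94 ± 0.38, the complement gene Hc at -2.66 ± 0.32 and the ATP-gated channel gene P2rx3 at -2.55 ± 0.25. The glycogen-binding Stbd1 (-2.29 ± 0.35) and the brush border aminopeptidase Anpep (-2.23 ± 0.35) followed in the authors' deposited table.

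Of 35 cytokine and NF-kB target genes, 10 rose and none fell in fibrin, with 12 risen when adjusted over the list alone (adjusted p = 2.1e-08). Complement C3 was at log2 2.20 ± 0.32, complement factor B (Cfb) at 2.14 ± 0.30, the alarmin Il33 at 2.14 ± 0.30 and the chemokine Cx3cl1 at 1.33 ± 0.28 in the authors' deposited table. Tubular injury and repair genes rose in 8 of 25 cases, 9 adjusted over the list alone, with adjusted p = 1.3e-07. Besides C3 these were led by Igfbp7 at 1.85 ± 0.23 and osteopontin (Spp1) at 1.47 ± 0.29 in the authors' deposited table. Fgb, the fibrinogen beta chain, rose by log2 1.39 ± 0.40 there, at a base mean of 29.4.

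For some genes the fold change implied by the base means, with the level in 2D taken from the other 3 tables, lay far above the deposited one in fibrin. The implied log2 value was above 1 and exceeded the deposited one by more than 1 for 28 of 11371 genes with a base mean of 100 or more in fibrin. This held for 1 of 11346 genes in Matrigel, 5 of 11293 in collagen I and 22 of 11394 in the printed cultures. In fibrin 16 of the 28 did not pass, and they included 5 of the 24 cytokine genes above that base mean, while 3 of the 22 such injury genes were also among the 28. Steap4, an iron reductase, had an implied log2 value of 7.71 and 0.31 ± 0.24 in the authors' deposited table, and lipocalin 2 (Lcn2) 4.93 and 1.07 ± 0.37. Serum amyloid A3 (Saa3) had 2.85 and 0.32 ± 0.30, and the chemokines Cxcl5 and Ccl2 had 4.23 and 4.12 against 1.05 ± 0.37 and 0.41 ± 0.28 in the authors' deposited table. These 5 genes were chosen after their values were seen. Their base means in fibrin ran from 491 for Ccl2 to 35587 for Cxcl5, which argues against few reads as the source of the gap in these 5. A wide spread between replicates is the likelier source for them. Which of the 3 fibrin libraries held the high counts cannot be read from the tables, so the fibrin cytokine and injury results could not be repeated without a library.

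Replication genes rose in 29 of 32 cases in fibrin and in all 32 adjusted over the list alone, and the list passed with adjusted p = 2.9e-41. Rrm2 at log2 1.72 ± 0.24, the replicative helicase subunit Mcm4 at 1.41 ± 0.21 and the sliding clamp Pcna at 1.23 ± 0.22 stood out in the authors' deposited table. Mitotic genes rose in 21 of 30 cases (27 adjusted over the list alone, adjusted p = 1.2e-21). Cholesterol genes rose in 14 of 25 cases (21 adjusted over the list alone, adjusted p = 1.5e-22). Idi1 was at 2.27 ± 0.24 and Insig1, which holds back sterol synthesis, at 1.76 ± 0.21 in the authors' deposited table. Hypoxia and glycolysis genes fell in 11 of 35 cases, 14 adjusted over the list alone, and the list was lower with adjusted p = 1.4e-14. Ankrd37 at -1.91 ± 0.22, the prolyl hydroxylase P4ha2 at -1.78 ± 0.29 and the pyruvate dehydrogenase kinase Pdk1 at -1.57 ± 0.22 fell in the authors' deposited table.

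Basement membrane genes fell in 5 of 29 cases in fibrin and rose in 1, with the same numbers adjusted over the list alone (adjusted p = 0.0017). Laminin alpha 3 (Lama3) was at log2 -2.22 ± 0.26 and laminin alpha 1 (Lama1) at 0.94 ± 0.23 in the authors' deposited table. After a correction for GC content and transcript length the list's adjusted p was 0.073. Smooth muscle and pericyte markers fell in 3 of 11 cases (3 adjusted over the list alone, adjusted p = 0.0019), with Mcam at -1.49 ± 0.23 and Notch3 at -1.23 ± 0.25 in the authors' deposited table. Proximal tubule genes went both ways, with 4 of 38 risen and 4 fallen in fibrin, 4 and 5 adjusted over the list alone. Kap at 1.99 ± 0.26 and the endopeptidase Mme at 1.70 ± 0.28 were the highest of them in the authors' deposited table. The epithelial transcription factor Ehf rose by 3.43 ± 0.34 there, while Cldn1 fell to -1.33 ± 0.28. Matrix proteases (2 risen and 6 fallen of 33, 3 and 8 adjusted over the list alone), mitochondrial respiration genes (none of 36 passed either way) and p53 targets (3 of 20 fallen, 1 risen and 4 fallen adjusted over the list alone) had adjusted p = 0.044, 0.013 and 0.039. With a preset correlation of 0.05 these were adjusted p = 0.21, 0.14 and 0.16.

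In all, 1215 of 14636 genes changed in fibrin in the authors' deposited table, 760 higher and 455 lower, and 610 had an absolute log2 fold change of 1 or more. The empirical null left 336 genes. It kept the 10 highest and lowest genes and 57 of the 84 named genes that had changed, 4 of the 10 cytokine genes, 3 of the 8 injury genes, 15 of the 29 replication genes, 4 of the 21 mitotic genes, 5 of the 14 cholesterol genes and 5 of the 11 hypoxia genes.

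**Figure D2:**
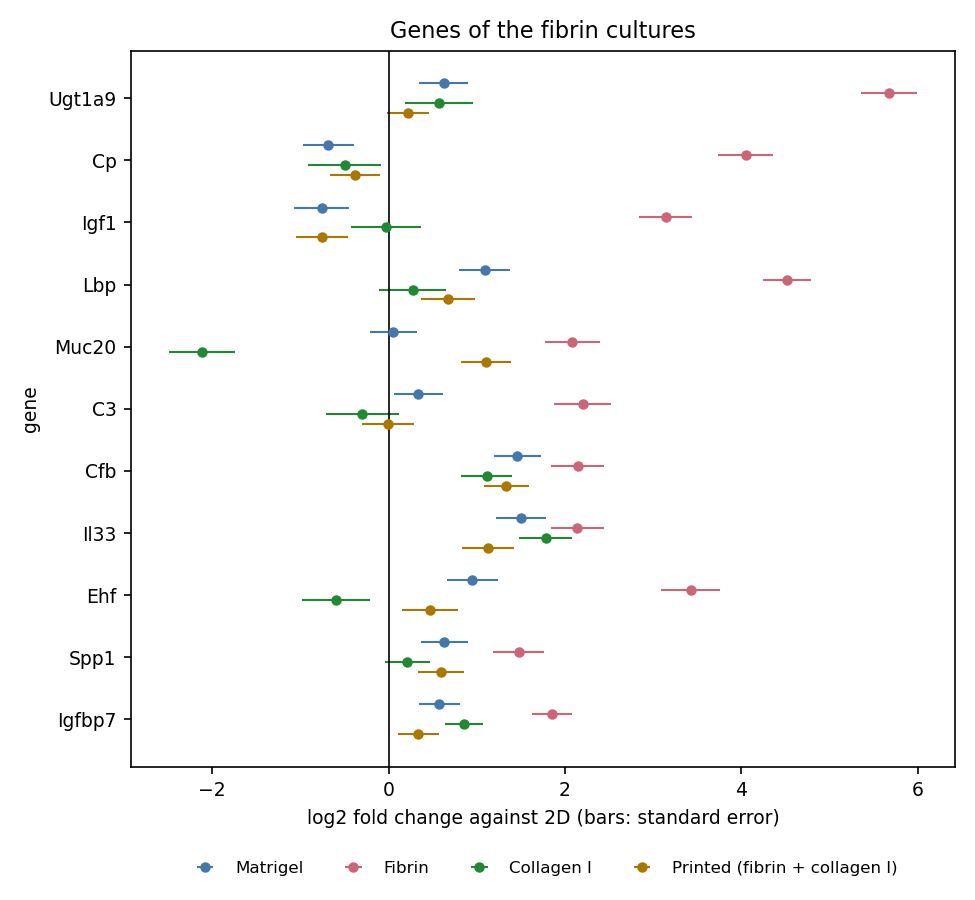
Log2 fold change against 2D, with the authors' standard error as bars, of 11 genes in the 4 microenvironments. Ugt1a9, Lbp and Cp reached 5.68, 4.52 and 4.05 in fibrin, while Cfb and Il33 were above 1 in every microenvironment.

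The comparison of collagen I with 2D gave the largest number of changed genes of the 4 by the authors' adjusted p, and the smallest under the empirical null. Replication, mitosis, sterol synthesis and respiration genes were higher in collagen I, and hypoxia, basement membrane, integrin and TGF-beta target genes were lower. Icos, a costimulatory receptor known from T cells, was highest among genes with a base mean of 100 or more, at log2 3.06 ± 0.30 in the authors' deposited table (chromosome 1, 60960773 to 61000322, GRCm38). Scel (2.95 ± 0.33) and Sprr2h (2.90 ± 0.31), both genes of the cornified envelope of squamous epithelia, Pcdh10 (2.92 ± 0.23), a protocadherin, and Tmem27 (2.87 ± 0.23), a partner of kidney amino acid transporters, came next in the authors' deposited table. The Sprr2 genes are close copies of one another, so the value of Sprr2h is uncertain. P4ha2, which hydroxylates prolines of collagens, fell most of these, to log2 -3.94 ± 0.36 or 15.3-fold, in the authors' deposited table (chromosome 11, 54100924 to 54131668). Ankrd37 at -3.40 ± 0.25, Pdk1 at -2.90 ± 0.28, Moxd1 at -2.76 ± 0.25 and Ostn at -2.76 ± 0.38 were the next lowest in the authors' deposited table.

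Of 35 hypoxia and glycolysis genes, 17 fell and none rose in collagen I, both over all genes and adjusted over the list alone. The list was lower with adjusted p = 5.2e-29. Besides P4ha2, Ankrd37 and Pdk1, the authors' deposited table had Pfkfb3, a regulator of glycolysis, at log2 -1.69 ± 0.20. Of 36 genes of mitochondrial respiration, 6 rose (7 adjusted over the list alone, adjusted p = 3.9e-05), among them cytochrome c (Cycs) at 0.76 ± 0.20 and Ndufa5 at 0.78 ± 0.21 in the authors' deposited table. Replication genes rose in 31 of 32 cases and in all 32 adjusted over the list alone (adjusted p = 3.8e-43), led by Rrm2 at 2.00 ± 0.26 and Cdc6, which licenses replication origins, at 1.80 ± 0.30 in the authors' deposited table. Mitotic genes rose in 22 of 30 cases, 26 adjusted over the list alone, with adjusted p = 2.2e-23. Cholesterol genes rose in 16 of 25 cases (20 adjusted over the list alone, adjusted p = 1.5e-22), and Idi1 stood at 2.44 ± 0.25 in the authors' deposited table.

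Basement membrane genes fell in 9 of 29 cases in collagen I and rose in 1, 11 and 1 adjusted over the list alone (adjusted p = 4.1e-05). Laminin beta 3 (Lamb3) fell to log2 -1.61 ± 0.25 and Col4a5 to -1.32 ± 0.25, and nidogen (Nid1) rose to 0.94 ± 0.22 in the authors' deposited table. Integrins and matrix receptors fell in 5 of 29 cases, 7 adjusted over the list alone, with adjusted p = 0.00062. Itga2, a subunit of a collagen-binding integrin, was at -1.15 ± 0.33 and Itgb5 at -1.07 ± 0.25 in the authors' deposited table. TGF-beta target genes fell in 6 of 22 cases and rose in 2, 9 and 3 adjusted over the list alone (adjusted p = 1.4e-05). Mesenchymal and fibroblast genes fell in 8 of 31 cases and rose in 2, with the same numbers adjusted over the list alone and adjusted p = 0.00062. Their adjusted p was 0.081 when ranks were tested. Col1a1, a chain of collagen I itself, was at -2.35 ± 0.33, Fn1 at -1.73 ± 0.26 and cadherin 11 (Cdh11) at -1.92 ± 0.31 in the authors' deposited table. Matrix proteases fell in 8 of 35 cases, 2 risen and 12 fallen adjusted over the list alone (adjusted p = 0.00036), with Timp3 at -1.45 ± 0.22 in the authors' deposited table.

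Interferon response genes fell in 3 of 34 cases in collagen I (3 adjusted over the list alone, adjusted p = 0.00039), but their adjusted p was 0.099 among genes with a base mean of 100 or more. Epithelial junction and polarity genes fell in 6 of 52 cases, with 6 adjusted over the list alone and adjusted p = 0.0025, or adjusted p = 0.088 with a preset correlation of 0.05. Cldn1 at log2 -1.99 ± 0.21 and keratin 8 (Krt8) at -0.92 ± 0.28 were among them in the authors' deposited table. Smooth muscle and pericyte markers fell in 1 of 12 cases, 3 adjusted over the list alone, with adjusted p = 0.013 and adjusted p = 0.068 after the GC and length correction. Mcam was at -0.92 ± 0.29 in the authors' deposited table. Actin and SRF/MRTF targets (1 risen and 1 fallen of 29, the same adjusted over the list alone) and heat shock genes (2 of 20 risen, 3 adjusted over the list alone) had adjusted p = 0.044 and 0.049. These became adjusted p = 0.20 and 0.18 with a preset correlation of 0.05. Proximal tubule genes did not shift as a list, with 3 of 39 risen and 4 fallen (4 and 5 adjusted over the list alone), and Kap was at 2.86 ± 0.27 and Anpep at -2.46 ± 0.35 in the authors' deposited table.

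In all, 1570 of 14064 genes changed in collagen I in the authors' deposited table, 916 higher and 654 lower (58.3% higher), and 717 had an absolute log2 fold change of 1 or more. The empirical null left 146 genes, 64 higher and 82 lower, or 43.8% higher, so the balance of directions depends on that choice. It kept the 10 highest and lowest genes but only 34 of the 105 named genes that had changed, 6 of the 31 replication genes, 1 of the 22 mitotic genes and 3 of the 16 cholesterol genes. None of the 6 respiration genes and none of the 5 integrin genes passed there, and 1 of the 9 fallen basement membrane genes and 6 of the 17 hypoxia genes did.

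**Figure D3:**
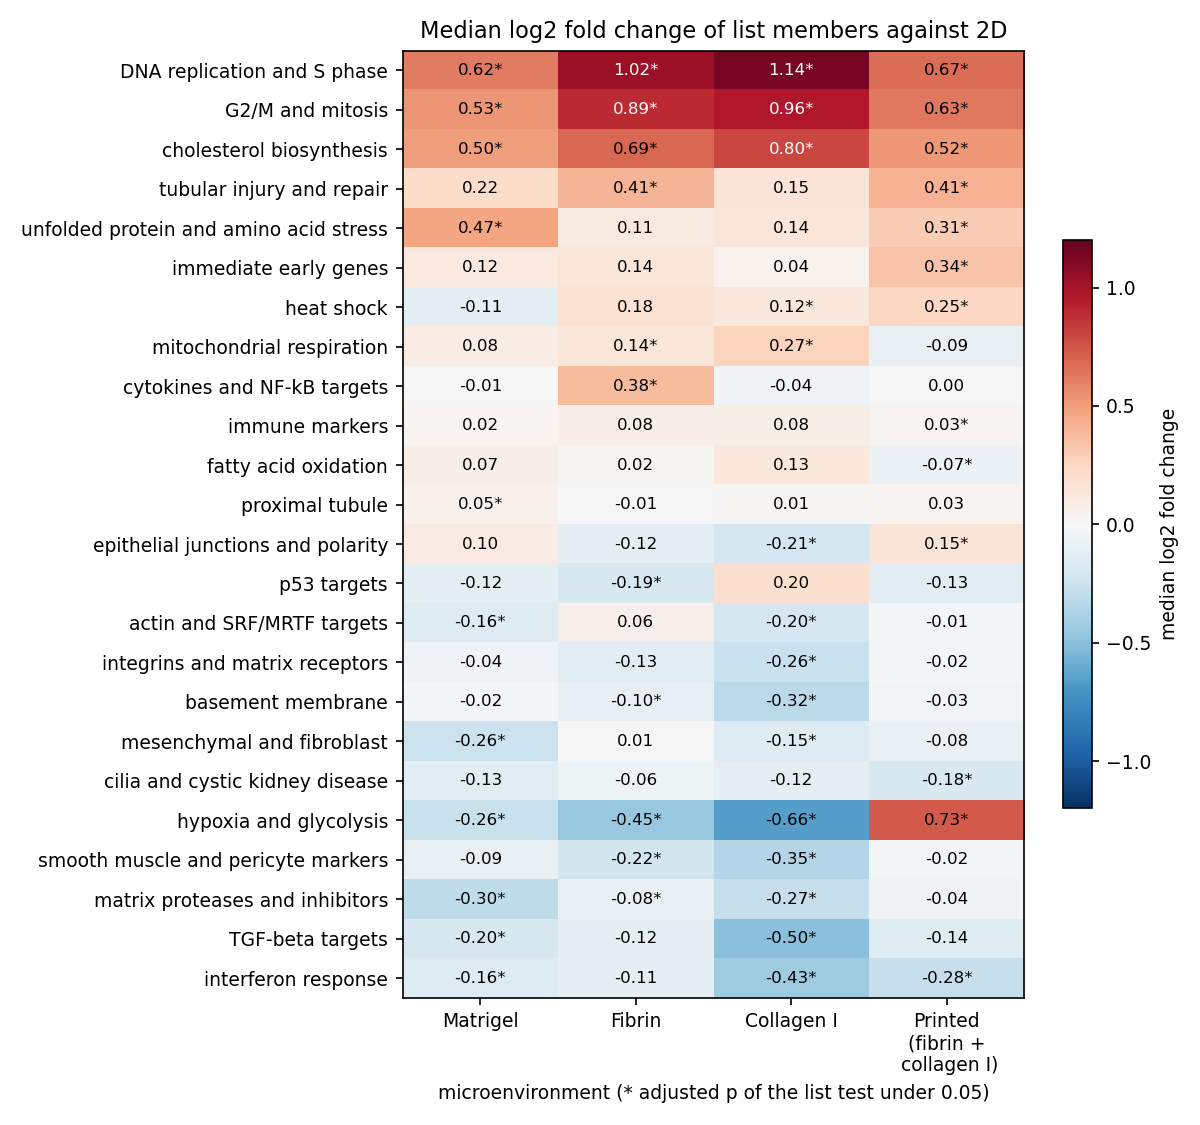
Median log2 fold change against 2D of the members of 24 gene lists in the 4 microenvironments, red where higher and blue where lower than in 2D, with a star where the list test had an adjusted p under 0.05. The hypoxia list is at 0.73 in the printed cultures and at -0.66 in collagen I.

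The printed cultures differed from 2D in the dispensing method and in the gel, by the labels fibrin and collagen I, and the comparison cannot separate the 2. Hypoxia and glycolysis genes were higher there, as were replication, mitosis and sterol synthesis genes, and far fewer genes were lower than higher. Abcg1, an exporter of sterols, was highest by a wide margin among genes with a base mean of 100 or more, at log2 3.80 ± 0.26 in the authors' deposited table (chromosome 17, 31057694 to 31117984, GRCm38). Olfm1 at 2.36 ± 0.24, the fatty acid hydroxylase Fa2h at 2.26 ± 0.30, the phospholipid transporter Abcb4 at 2.22 ± 0.27 and Icos at 2.15 ± 0.31 followed in the authors' deposited table. The lowest of these were Oas1e (-1.69 ± 0.30), Prrt4 (-1.67 ± 0.29), the angiopoietin Angpt4 (-1.66 ± 0.31), Nox4 (-1.64 ± 0.32) and Plxdc1 (-1.64 ± 0.29) in the authors' deposited table. Oas1e belongs to a cluster of near copies, which makes its value uncertain.

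Of 35 hypoxia and glycolysis genes, 17 rose and none fell in the printed cultures, and 26 rose when adjusted over the list alone (adjusted p = 6.1e-32). P4ha2 was at log2 1.46 ± 0.30, the phosphofructokinases Pfkp and Pfkl at 1.04 ± 0.20 and 1.05 ± 0.23 and the mutase Pgam1 at 0.93 ± 0.21 in the authors' deposited table. For 2 of 32 members with a base mean of 100 or more, Ankrd37 and Aldoc, chosen after their values were seen, the base means implied a log2 value above 1 that exceeded the deposited one by more than 1, and neither passed. Replication genes rose in 13 of 32 cases (26 adjusted over the list alone, adjusted p = 1.3e-31), with Rrm2 at 1.29 ± 0.20 and Tk1 at 1.07 ± 0.21 in the authors' deposited table. Mitotic genes rose in 10 of 30 cases, 22 adjusted over the list alone, with adjusted p = 9.7e-24. Cholesterol genes rose in 10 of 25 cases (16 adjusted over the list alone, adjusted p = 3.5e-19), with Idi1 at 1.68 ± 0.24 and the synthase Hmgcs1 at 0.93 ± 0.20 in the authors' deposited table.

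Immediate early genes, which answer growth factor and mechanical signals within minutes to hours, rose in 3 of 24 cases in the printed cultures (7 adjusted over the list alone, adjusted p = 4.6e-07). The authors' deposited table had the phosphatase Dusp6 at log2 1.09 ± 0.20, Klf2 at 1.37 ± 0.30 and Egr3 at 1.10 ± 0.31. Tubular injury genes rose in 2 of 25 cases, 5 adjusted over the list alone (adjusted p = 6.6e-05), namely keratin 20 (Krt20) at 1.10 ± 0.20 and Sprr1a at 1.17 ± 0.26 in the authors' deposited table. The injury marker Havcr1, chosen after its values were seen, did not pass, at 0.47 ± 0.27 in the authors' deposited table, while its base means implied 2.62. It was the only 1 of 21 injury genes with a base mean of 100 or more whose implied log2 value was above 1 and exceeded the deposited one by more than 1, and Fosl1, also chosen so, the only 1 of 23 immediate early genes. Amino acid and unfolded protein stress genes had 2 of 30 risen and 1 fallen, the same adjusted over the list alone, with adjusted p = 4.3e-05. The hormone Fgf21 was at 1.40 ± 0.33 and the stress factor Ddit3 at -0.70 ± 0.21 in the authors' deposited table. Heat shock genes were higher with 1 of 20 risen (2 adjusted over the list alone, adjusted p = 0.00062), the chaperone Hsph1 at 0.77 ± 0.20 in the authors' deposited table. Interferon response genes were lower with adjusted p = 0.00033, although 1 of 34 rose and 1 fell, also adjusted over the list alone. These were Oasl1 at 1.32 ± 0.32 and Ifit1 at -1.05 ± 0.31 in the authors' deposited table. Fatty acid oxidation genes were lower with 1 of 30 fallen (2 adjusted over the list alone, adjusted p = 0.0025), the thioesterase Acot2 at -0.77 ± 0.23 in the authors' deposited table.

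Epithelial junction genes rose in 3 of 52 cases in the printed cultures, 3 adjusted over the list alone, with adjusted p = 0.013 and adjusted p = 0.18 with a preset correlation of 0.05. Keratin 19 (Krt19) was at log2 1.34 ± 0.20, claudin 4 (Cldn4) at 1.51 ± 0.32 and Muc1 at 0.83 ± 0.24 in the authors' deposited table, and Cldn4 had a base mean of 53.2. Immune markers, a list of other cell types, rose in 2 of 12 cases (2 adjusted over the list alone, adjusted p = 0.049, or adjusted p = 0.14 with a preset correlation of 0.05). The risen members were the macrophage genes Cd68, 3.03-fold higher, and Csf1r at log2 0.71 ± 0.22 in the authors' deposited table, with base means of 944 and 722. Csf1r did not pass when adjusted over every gene with a p, and 1 of the 2 passed under the empirical null. In Matrigel and in collagen I Csf1r fell, the only 1 of 13 markers that changed there. Only 5 of the 13 in Matrigel and 4 in collagen I had an adjusted p. None of 49 genes of cilia and cystic kidney disease passed, also adjusted over the list alone, while the list was lower with adjusted p = 0.0014 and adjusted p = 0.061 with a preset correlation of 0.05.

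In all, 481 of 15116 genes changed in the printed cultures in the authors' deposited table, 379 higher and 102 lower, and 228 had an absolute log2 fold change of 1 or more. The empirical null left 270 genes. It kept the 10 highest and lowest genes and 56 of the 73 named genes that had changed, 9 of the 17 hypoxia genes, 9 of the 13 replication genes, 5 of the 10 mitotic genes and 4 of the 10 cholesterol genes.

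**Figure D4:**
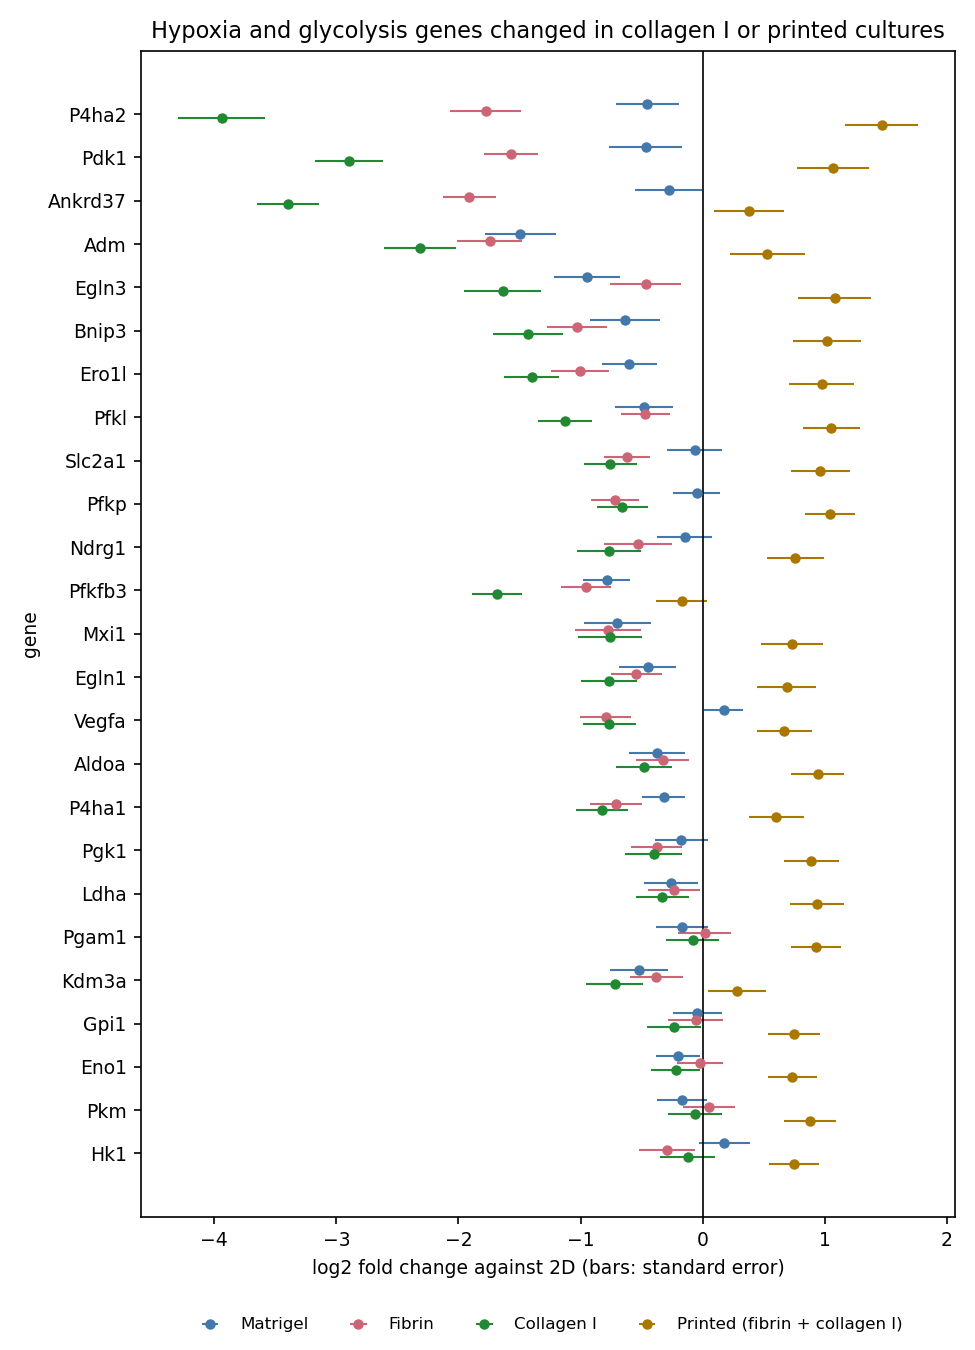
Log2 fold change against 2D, with the authors' standard error as bars, of the 25 hypoxia and glycolysis genes that changed in collagen I or in the printed cultures. P4ha2 is at -3.94 in collagen I and at 1.46 in the printed cultures, and most genes lie left of 0 in collagen I and fibrin.

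The microenvironments were then compared with one another, by the difference of their fold changes against 2D over the combined standard error. The 2 fold changes share the libraries in 2D, and leaving this out of the error makes the test more conservative. Deposited errors that are too small, or strong shrinkage in 1 table alone, would work the other way. Of the 4 largest differences towards the printed cultures against collagen I, 3 were in genes of the hypoxia list, all but Mgarp. P4ha2 was higher in the printed cultures by log2 5.40 ± 0.46 (adjusted p = 4.8e-27), Mgarp, a mitochondrial protein, by 4.17 ± 0.50, Pdk1 by 3.97 ± 0.40 and Ankrd37 by 3.78 ± 0.38, from the authors' deposited tables. Kap (difference -2.35 ± 0.41), Pcdh10 (-2.21 ± 0.38), Tmem27 (-1.85 ± 0.37) and Sprr2h (-1.73 ± 0.44) were lower in the printed cultures, from the same deposited tables of the authors. The difference in Pcdh10 is uncertain: in the printed cultures its base means implied log2 2.29, against 0.71 ± 0.30 in the authors' deposited table. That in Ankrd37 is uncertain in size, with 1.65 implied against 0.38 ± 0.29 in the same deposited table of the authors. In all 125 of 18894 genes differed, 115 of them higher in the printed cultures. The hypoxia list differed with adjusted p = 2.2e-108, and replication genes were lower in the printed cultures than in collagen I by a median of log2 -0.51 with adjusted p = 3.4e-12.

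Between printed and fibrin cultures 198 of 18859 genes differed, 106 higher in the printed and 92 higher in the fibrin cultures, or 64 and 67 with an adjusted p under 0.01. P2rx3 was higher in the printed cultures by log2 3.46 ± 0.37, Hc by 3.41 ± 0.45, P4ha2 by 3.24 ± 0.42 and Abcg1 by 3.07 ± 0.45, from the authors' deposited tables. Ugt1a9 (-5.46 ± 0.40), Cp (-4.43 ± 0.42), Igf1, the insulin-like growth factor, (-3.89 ± 0.42) and Lbp (-3.85 ± 0.41) were lower there than in fibrin, from the authors' deposited tables. For Abcg1 in printed cultures and Ugt1a9, Cp and Igf1 in fibrin, base means implied log2 values more than 1 above the deposited ones. The size of their differences is uncertain here and below. Cytokine and NF-kB targets were lower in the printed cultures than in fibrin by a median of log2 -0.44 with adjusted p = 1.8e-07, although the labels of the printed cultures also give fibrin.

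Between Matrigel and collagen I 62 of 18837 genes differed, 53 of them higher in Matrigel. P2rx3 was higher in Matrigel by log2 4.01 ± 0.37, P4ha2 by 3.48 ± 0.44, Ankrd37 by 3.12 ± 0.37 and the secreted serpin Serpinf1 by 2.75 ± 0.48, from the authors' deposited tables. Mesothelin (Msln, -1.95 ± 0.42), the adhesion molecule Nrcam (-1.59 ± 0.41), the ubiquitin hydrolase Uchl1 (-1.42 ± 0.37) and Klhl13 (-1.39 ± 0.33) were lower in Matrigel, from the authors' deposited tables. Epithelial junction genes were higher in Matrigel than in collagen I by a median of log2 0.23 with adjusted p = 4.7e-08, and proximal tubule genes by 0.18 with adjusted p = 4.8e-05.

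Between Matrigel and fibrin 167 of 18844 genes differed, 59 higher in Matrigel and 108 higher in fibrin. P2rx3 (4.06 ± 0.31), the inner ear gene Otog (2.92 ± 0.48), the receptor phosphatase Ptprb (2.53 ± 0.40) and Anpep (2.27 ± 0.45) were higher in Matrigel, and Ugt1a9 (-5.05 ± 0.43), Cp (-4.73 ± 0.43), Igf1 (-3.90 ± 0.44) and Lbp (-3.43 ± 0.40) lower, as log2 differences from the authors' deposited tables. Actin and SRF/MRTF targets were lower in Matrigel than in fibrin with adjusted p = 0.00019 and a median difference of log2 -0.19.

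Between collagen I and fibrin 90 of 18867 genes differed, 82 of them higher in fibrin. These included Ugt1a9 at a difference of log2 -5.10 ± 0.50, Cp at -4.55 ± 0.52, Lbp at -4.25 ± 0.47 and the membrane mucin Muc20 at -4.20 ± 0.48, from the authors' deposited tables. Msln (2.02 ± 0.44), Nrcam (1.87 ± 0.44), the natriuretic peptide receptor Npr3 (1.48 ± 0.38) and the amino acid transporter Slc6a18 (1.30 ± 0.34) were higher in collagen I, from the authors' deposited tables. TGF-beta targets were lower in collagen I than in fibrin by a median of log2 -0.44 with adjusted p = 3.3e-05.

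Between Matrigel and printed cultures 82 of 18854 genes differed, 19 higher in Matrigel and 63 higher in the printed cultures. Kap was higher in Matrigel by log2 2.51 ± 0.41, the fatty acid hydroxylase Cyp4a10 by 2.11 ± 0.41, the carboxylesterase Ces2b by 1.96 ± 0.39 and Pcdh10 by 1.91 ± 0.37, from the authors' deposited tables, with the value of Pcdh10 uncertain as said above. Abcg1 (-3.79 ± 0.41), the osmolyte transporter Slc6a12 (-2.81 ± 0.44), Hc (-2.69 ± 0.43) and Mgarp (-2.46 ± 0.43) were lower in Matrigel, from the authors' deposited tables. The size of the difference in Slc6a12 is uncertain too, with log2 3.85 implied in the printed cultures against 1.97 ± 0.32 in the authors' deposited table. Over all 6 pairs 88 of 192 list tests passed, and 61 did with a preset correlation of 0.05. With a correlation of 0.5 between the 2 fold changes, as a shared control of equal precision gives, the number of differing genes rose to between 286 and 735 per pair.

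A set of genes moved the same way in all 4 comparisons. Of 14020 genes tested in all of them, 113 were higher and 30 lower in every microenvironment. The higher ones included Icos, Ugt1a7c, Prkar2b, a regulatory subunit of protein kinase A, Gsta4, a glutathione transferase, Nefh, a neurofilament chain, and Pclaf, a partner of the sliding clamp. The smallest of their 4 log2 values were 1.77 ± 0.28 for Icos in Matrigel and 1.51 ± 0.21 for Prkar2b in Matrigel in the authors' deposited tables. Plxdc1, Prrt4, Jakmip1, Fbln7, Nox4 and Oas1e were lower in all 4. Independent lists would share 0.0516 higher and 0.00373 lower genes, and unchanged groups against common controls shared 27.7 and 8.9 in simulation with lists of the same sizes. The simulation left out that all groups came from the same passages and a common pool of cells. The 3 libraries in 2D are too few to be split between the comparisons, so part of the excess may come from the shared controls.

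In pairs, collagen I and fibrin shared 459 higher and 303 lower genes, against 212 and 121 in the simulation of shared controls and 46.9 and 21.2 for independent lists. Printed and fibrin cultures shared 169 and 43, against 109 and 32.7 in the simulation and 19.0 and 3.20 for independent lists. Across 11242 genes with a base mean of 100 or more, the covariance of log2 fold changes of collagen I and fibrin was 0.167, against 0.0294 from shared controls alone. For printed and fibrin cultures it was 0.0757 against 0.0280 across 11261 genes, and the correlation of the Wald statistics, 0.486, lay below the simulated 0.499. Genes are not independent replicates, so these values carry no p. Of the genes that changed in 1 comparison and in no other (317 in Matrigel, 355 in fibrin, 565 in collagen I and 127 in the printed cultures), 4, 33, 2 and 7 differed from all 3 other microenvironments in the difference test.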

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

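All tests of explanations in this part were chosen after the hypoxia result was seen, and for GC content and length the outcome of the test itself had not been seen. Each result below drew attention because 2 microenvironments lay on opposite sides of 2D, both past the threshold, and a test of their difference passed. For single genes the value is the difference of log2 fold changes from the authors' deposited tables.

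Hypoxia and glycolysis genes as a list were above 2D in the printed cultures and below it in the other 3 microenvironments. The list differed with adjusted p = 2.22e-108 between printed and collagen I cultures, 6.75e-71 between printed and fibrin cultures and 1.57e-63 between Matrigel and printed cultures. P4ha2 differed by log2 5.40 between printed and collagen I cultures and by 3.24 between printed and fibrin cultures in the authors' deposited tables. Mgarp, which is not in the list, differed by 4.17 between printed and collagen I cultures and by -2.46 between Matrigel and printed cultures, and Pdk1 by 3.97 between printed and collagen I cultures, in the same deposited tables of the authors.

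Epithelial junction and polarity genes were above 2D in the printed and below it in the collagen I cultures, and the list differed with adjusted p = 2.95e-08. Each of the 2 calls against 2D ended with a preset correlation of 0.05 (adjusted p = 0.18 and 0.088), while the difference itself passed there with adjusted p = 0.00085. The channel gene P2rx3 differed by log2 3.46 between printed and fibrin cultures, by 4.01 between Matrigel and collagen I and by 4.06 between Matrigel and fibrin in the authors' deposited tables. It was above 2D in Matrigel (1.51 ± 0.18) and in the printed cultures (0.91 ± 0.27) and below it in fibrin (-2.55 ± 0.25) and collagen I (-2.50 ± 0.33) in the authors' deposited tables. The mucin gene Muc20 fell in collagen I (-2.12 ± 0.37), rose in fibrin (2.08 ± 0.31) and differed by -4.20 between them in the authors' deposited tables.

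The opposite hypoxia list in printed and collagen I cultures had a median difference of log2 1.42 with a median standard error of 0.33. All genes with an adjusted p in both comparisons had a median difference of -0.02 (-0.0196), so the list moved relative to most genes. A shift in normalization is not tested by this, because scaling by size factors places the median of all genes near 0. A trend with GC content and length as the whole cause is argued against by adjusted p = 8.79e-118 after that correction, and a change confined to glycolytic enzymes and glucose transporters by adjusted p = 1.52e-76 in the 15 other members. A difference in oxygen supply or cell density between the cultures is consistent with these values and may underlie them, but neither was measured in the tables, and high values in few printed libraries stay open, since 2 of 32 members had implied fold changes far above the deposited ones. Dispensing method and gel changed together in the printed cultures, so which of them goes with the pattern was not tested.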

How the results depend on the processing

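No paired analysis was possible because the tables hold no values per library. Leaving out 1 replicate, a replicate block, another normalization, an estimated correlation between genes and other splits of the samples were not run for the same reason. No list call that also passed under an alternative changed direction there. For named genes this could not be tested, because every alternative kept the sign of the deposited fold change. The balance of directions turned in 2 counts: collagen I had 64 higher and 82 lower genes under the empirical null against 916 and 654, and printed against fibrin cultures 64 and 67 with an adjusted p under 0.01 against 106 and 92, for causes that were not tested. The adjustment over every gene with a p and minimum base means of 10 and 100 left the counts of changed genes within 1.5 times the main ones. An adjusted p under 0.01, a stricter threshold by construction, left 539 changed genes in Matrigel, 724 in fibrin, 887 in collagen I and 256 in the printed cultures, and an absolute log2 fold change of 1 or more left 323, 610, 717 and 228. The empirical null left 373, 336, 146 and 270, because its scales were above 1 and widest for collagen I, which therefore had the fewest genes instead of the most. Whether that spread reflects many small changes or errors that are too small was not tested. Of the 345 named calls, 204 passed under the empirical null and 141 did not. Adjustment over every gene ended 10: Ifit1 in Matrigel, Herpud1, Zmat3, Flt1 and Des in fibrin, Gadd45a, Psph and Plk3 in collagen I, and Scnn1g and Csf1r in the printed cultures.

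A correlation of 0.5 between estimates, which narrows the error by construction, raised the differing genes to 589 for printed against collagen I, 735 for printed against fibrin, 509 for Matrigel against collagen I, 666 for Matrigel against fibrin, 286 for collagen I against fibrin and 415 for Matrigel against printed cultures. With an adjusted p under 0.01 they were 76 for printed against collagen I, 131 for printed against fibrin, 88 for Matrigel against fibrin and 46 for Matrigel against printed cultures. Genes shared by all 4 comparisons came to 58 higher and 12 lower with an adjusted p under 0.01, and to 34 and 15 with an absolute log2 fold change of 1 or more. Shared genes in pairs were 135 and 115 under these thresholds for printed and collagen I, 96 and 80 for printed and fibrin, 277 and 176 for Matrigel and collagen I, 212 and 146 for Matrigel and fibrin, 413 and 330 for collagen I and fibrin, and 119 and 87 for Matrigel and printed cultures. Of 50 list calls against 2D, 40 held and 10 were lost with a preset correlation of 0.05, 44 and 6 on log2 fold changes (1 gained), 46 and 4 on ranks (3 gained) and 44 and 6 after GC content and length. With a base mean of 100 or more, where 112 of 128 tests could be run, 42 held, 5 were lost, 3 were not tested and 4 were gained. Of 88 list calls between microenvironments, 61 held and 27 were lost with a preset correlation of 0.05, and 81 and 7 after GC content and length (1 gained). These last 2 and the GC and length correction against 2D were chosen after seeing the data.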

Other observations

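All tests of explanations in this part were chosen after the patterns had been seen, and for GC content and for unseen members the outcome of the test itself had not been seen.

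Several kidney genes moved in lists that were not called in the same comparison. Among distal tubule and collecting duct genes, carbonic anhydrase Car2 rose by log2 1.69 ± 0.23 and the anion exchanger Slc26a4 by 1.73 ± 0.40 in fibrin in the authors' deposited table. Scnn1g fell there, so that 2 of 26 genes rose and 1 fell in fibrin, where 14 had an adjusted p. Scnn1g fell in Matrigel and collagen I too. It also changed in the printed cultures, where 1 of 26 genes of this list rose and 1 fell, but not when adjusted over every gene with a p. Sodium channel subunit Scnn1a fell to -1.45 ± 0.33 in collagen I and the kinase gene Wnk4 rose by 0.89 ± 0.16 in Matrigel in the authors' deposited tables. Pkhd1, the gene of recessive polycystic kidney disease, fell to -0.53 ± 0.16 in Matrigel, -1.05 ± 0.20 in fibrin and -1.05 ± 0.23 in collagen I in the authors' deposited tables. Cys1, a gene of cystic kidneys in mice, fell to -0.97 ± 0.30 in fibrin and -0.91 ± 0.29 in collagen I there, as the authors' deposited tables give it. In the printed cultures none of 49 cilia and cystic kidney disease genes passed, while the list was lower with adjusted p = 0.0014, or 0.061 with a preset correlation of 0.05.

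Among developmental and signalling genes, the stem cell receptor Lgr5 rose by log2 1.93 ± 0.38 and the WNT effector Lef1 by 1.48 ± 0.36 in collagen I, both at base means under 100, and Wnt7a fell to -1.46 ± 0.34 in the authors' deposited table. Fgf9 rose by 1.14 ± 0.20 in Matrigel, and the Notch target Hey1 (1.51 ± 0.31) and Notch1 (1.02 ± 0.20) rose in fibrin, in the authors' deposited tables. Tgfb2 fell in all 4 comparisons, from -1.63 ± 0.26 in collagen I to -0.93 ± 0.25 in the printed cultures, in the authors' deposited tables. The plasminogen activator Plat rose by 1.43 ± 0.21 and thrombomodulin (Thbd) by 1.14 ± 0.28 in the printed cultures, and the urokinase receptor Plaur was 2.32-fold higher in collagen I, in the authors' deposited tables. Single markers of other cell types moved as well: Flt1 rose by 1.42 ± 0.24 in the printed cultures, Cd14 by 1.54 ± 0.22 in fibrin and Synpo fell to -1.16 ± 0.26 in collagen I in the authors' deposited tables. None of their lists passed there. Endothelial markers had 1 of 12 risen in the printed cultures (adjusted p = 0.19) and immune markers 2 of 12 in fibrin (adjusted p = 0.084). In each case only 6 of the 12 had an adjusted p. Podocyte markers had 1 risen and 2 fallen of 10 in collagen I (adjusted p = 0.27).

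Replication and S phase genes were higher in all 4 comparisons. In the printed comparison their median log2 fold change was 0.67, with a median standard error of 0.22, against 0.01 (0.0102) for all genes. Scaling by size factors places the median of all genes near 0, so a shift in normalization is not tested by it. GC content and length as the whole cause are argued against by adjusted p = 1.91e-30 in the printed comparison after correction. The shared libraries in 2D stay open as a source of the common rise: the microenvironments differed in the list, with a smallest adjusted p of 4.43e-14 over the 6 pairs, but low values in those 3 libraries would raise all 4 comparisons in any case, and Matrigel and printed cultures did not pass as different (adjusted p = 0.95). A higher share of dividing cells in the 3D cultures, or a denser and more arrested culture in 2D on day 7, may explain the pattern. Values relative to 2D do not separate these.

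Acute phase genes were higher in fibrin. The list was written after Lbp, Cp and others had been seen, and its 28 unseen members were higher with adjusted p = 0.00134, or 0.00116 after GC content and length, with 4 risen. Among these were lactoferrin (Ltf) at log2 2.26 ± 0.31, Zc3h12a at 1.70 ± 0.35 and A2m at 1.26 ± 0.33 in the authors' deposited table, named after their values were seen. Immune cells in the cultures are argued against by abundant leukocyte transcripts of the fixed list of immune markers, of which Ptprc had a base mean of 3.02, Lyz2 of 2.73 and Tyrobp and S100a9 of 0 in the authors' deposited table for fibrin, chosen after their values were seen. Other values go with such cells: Cd14 and Itgam rose, 2 of 12 markers, and the list was higher in fibrin than in Matrigel (adjusted p = 0.00095) and collagen I (adjusted p = 0.0035). The same list did not pass in fibrin against 2D (adjusted p = 0.084) or between printed and fibrin cultures (adjusted p = 0.60). High values in only some of the 3 fibrin libraries stay open as a source too: for 5 of 23 members the base means implied a log2 value above 1 that exceeded the deposited one by more than 1, and 2 of the 5 did not pass. A response of the cells to fibrin, or to plasma proteins or thrombin in that gel, may explain the pattern, and these were not separated.

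A candidate explanation for genes such as Nqo1 and Gsta4 is activity of the oxidative stress factor NRF2. Its 30 unseen targets were higher in collagen I with adjusted p = 4.31e-21, 16 of them risen, for example Srxn1 at log2 1.35 ± 0.22 and Hmox1 at 1.05 ± 0.22 in the authors' deposited table, chosen after their values were seen. The unseen targets were also higher in Matrigel (adjusted p = 1.01e-25), fibrin (1.33e-06) and the printed cultures (1.69e-20), so the pattern was shared by the 4 comparisons and may in part reflect the 2D cultures.

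Abcg1, Abca1 and Abcb4 in the printed cultures raised the question of the sterol sensor LXR. Its 15 unseen targets were higher there with adjusted p = 1.20e-05 and 4 risen: Apoc1 at log2 1.78 ± 0.32, Lpl at 0.98 ± 0.27, Scd1 at 0.87 ± 0.22 and Scd2 at 0.78 ± 0.22 in the authors' deposited table, named after their values were seen. LXR activity may be higher in the printed cultures, but it was not measured, and Srebf1, also a target, did not pass. Cholesterol biosynthesis genes were higher there too, with 10 of 25 risen, and these patterns were not separated. For squamous differentiation, raised by Sprr1b and Tgm1, the unseen members gave adjusted p = 0.118 in the printed cultures and 1 of 27 rose, so the wider list was not shown to change. Several members were near the floor there, such as Krt13, Krt14 and Krt16 with base means of 0.157, 1.05 and 1.47. Genes with so few reads add little to this test.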
